A study of Homo sapiens with 6 samples.

How the data were processed

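RNA was measured in 6 libraries of RUES2-derived neural tube organoids at day 6, 3 anterior and 3 posterior. Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a stranded messenger RNA kit for DNBSEQ sequencers. The submitters' processing notes name HISAT2 2.1.0, featureCounts 2.0.3 and the GRCh38 build. The strand setting and the annotation release are not given in the sources used here, so reads of overlapping and antisense genes cannot be separated with certainty. The authors deposited whole-number read counts per gene, not normalized, for 20658 Ensembl identifiers. Of these, 20657 had a symbol in the reference name table, 20473 were in GENCODE release 29 (GRCh38), which gave the coordinates, and 1786 had no count in any library. Columns were assigned to groups from the sample labels.

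Total counts per library were 31082200, 36455728 and 34097846 in anterior replicates 1, 2 and 3, and 41163917, 37869782 and 41336377 in posterior replicates 1, 2 and 3. A floor of 3 counts corresponded to between 0.0726 and 0.0965 CPM per library. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No library pair had identical values. Within a group, the chi-square per degree of freedom between libraries was 13.4 to 32.3, above sampling noise.

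The counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with the group, scaled by TMM and tested with the robust quasi-likelihood F test for posterior over anterior, with Benjamini-Hochberg adjustment and a threshold of 0.05. The standard error of a log2 fold change was taken from the fold change and its F statistic. The common biological coefficient of variation was 12.6%. A fold against a group with 0 counts is a lower bound that uses 3 counts over the group, and a fold against 1 to 3 counts is a ratio with a 95% counting interval. Set tests used camera on log2 CPM (prior count 2, preset correlation 0.01) over 33 lists of 478 entries, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move on balance one way, were run beside it. List counts are over all genes tested. Adjusted over the list alone, they were the same except for 7 genes up in the retinoic acid list, 8 up in the YAP and TAZ list, 7 down in the cadherin list, 5 down in the endoderm list, 4 down in the Hedgehog list and 3 down in the RNA quality list. In the lists, 13 genes stand in more than 1 list.

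The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. Genes were named if they were among the 10 largest fold changes in each direction past the threshold, with at least 5 CPM in the higher group and no overlap between the groups. Genes known only by an Ensembl identifier, and those with LOC, LINC, clone-style or open reading frame (orf) symbols, were left out of this ranking. Up to 4 members per list with the smallest adjusted p and at least 1 CPM were also named, together with 15 genes fixed by name whatever their values. Some genes that this rule names are not reported here. Other genes were chosen after their values were seen, and this is said where it applies. XIST and Y-linked genes are not named.

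The scripts were tested on simulated data made from these libraries. Over 15877 genes with 200 changed, the test recovered 52.2% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 97.0% of those changed 4-fold, and 17 calls (9.61%) were false. Over 15982 genes, camera called 4 of 4 shifted lists and 0 of 26 without a shifted member. Genes were simulated independently of each other, whereas the correlation estimated within the real lists reached 0.954. The simulation therefore does not show how often correlated lists are called falsely. Its 200 changed genes are also far fewer than the 9934 called in the data.

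The groups share replicate numbers in the labels. The deviations from the group means of same-numbered libraries correlated across genes at 0.156, 0.195 and 0.147 for numbers 1, 2 and 3, all above 0.1, so the numbers were treated as pairing the libraries and a fit with the number as a block was run as an alternative. The pairing comes from this check of the data, as the labels do not say what a number stands for. Deviations from a group mean cancel out within the group, so these correlations are not independent of each other and cannot establish pairing. The main tests used no block. Other alternatives were DESeq2-style size factors, total counts alone, upper-quartile factors, no filter, a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, no robust estimation, a test beyond 1.5-fold (glmTreat) and each library left out in turn. Counts of list members without posterior replicate 3 and without anterior replicate 1, and ratios from counts without each library in turn, were added after the data were seen.

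The rule for the test of carried-over reads in the closing section was rewritten and has 5 forms in all, each later form written after its values were seen. The first form compared 1 set of genes per library and asked for at least 0.8 of the reference share, the second asked for 0.8 to 1.25 of it, and the third took the lowest share over 12 sets of genes with an interval widened to 99.6%. The fourth also asked the shares of single HOX genes to agree within counting noise, and was dropped because libraries of a group differ by more than counting noise. The form used keeps the interval of the third, and says that carry-over fits where the shares of all 12 sets lie within 0.8 to 1.25 of the reference. As each set gives only an upper limit for carry-over, a share above this range does not speak against it. The 5 forms gave different readings for the anterior replicates, and the same reading for posterior replicate 3. The tests of motile cilia genes and of stem cells in posterior replicate 3 were also rewritten after their values were seen. The first form counted all 24 motile cilia genes and all 12 pluripotency genes, and the form used leaves out the genes noticed before the test. A test of floor plate cells by the level of NOTO was dropped, as NOTO belongs to the pattern.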

Results

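The series measured messenger RNA in human neural tube organoids, which are small epithelial structures with a lumen grown from RUES2, an established human embryonic stem cell line. Organoids were collected at day 6 of culture in 2 groups of 3 libraries. Anterior organoids received inhibitors of BMP and TGF-beta signalling from day 2 to day 3. Posterior organoids received a WNT activator for 24 h, followed for 48 h by activators of the WNT, FGF and retinoic acid pathways together with a BMP inhibitor. The series title concerns cell intercalation during lumen formation, and the comparison open to these libraries was the posterior against the anterior programme. Total gene counts ran from 31082200 in anterior replicate 1 to 41336377 in posterior replicate 3. Between 17588 and 17875 genes had at least 1 count in a library. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Values are CPM, counts scaled to the effective library size, given as mean ± SD with n = 3 per group, and fold changes come from the edgeR fit with its Benjamini-Hochberg adjusted p-values.

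The groups differed in a large part of the transcriptome. Posterior organoids expressed HOX, CDX, PAX3, NCAM1 and CDH2, whereas anterior organoids expressed forebrain transcription factors together with POU5F1, E-cadherin, FOXA2 and NOTO. Of 15982 genes tested, 4879 were higher in posterior and 5055 were higher in anterior organoids. With a change of at least 2-fold, these numbers were 1663 and 2167, and with at least 32-fold they were 109 and 214. When the test asked for a change beyond 1.5-fold, 1968 genes were higher in posterior and 2352 in anterior organoids. The first principal component of log2 CPM held 91.4% of the variance and separated the groups. Mitochondrial genes took 5.60% ± 0.43 of the counts in anterior and 4.86% ± 0.39 in posterior libraries (SD, n = 3, two-sided exact permutation p = 0.2, where the smallest possible p is 0.1). The set tests below used camera with a preset correlation between genes, and 18 of the 33 lists passed. Fry, where named, tests a list against no change. With an estimated correlation 0 lists passed, and the smallest adjusted p was 0.395, as given with each group. The estimate was below the preset 0.01 in some lists that lost their call, at -0.0292 for forebrain, -0.0715 for midbrain and -0.00147 for apicobasal polarity genes. In these lists the loss did not come from a higher correlation. Lists of unlike correlation share the value 0.395 because the Benjamini-Hochberg adjustment gave them a common adjusted p. It is therefore not a measure of each list by itself.

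HOX genes, the transcription factors that set position along the body axis, differed between the groups along most of their clusters. All 12 tested members of HOX paralog groups 1-4 rose in posterior organoids (camera adjusted p = 6.18e-07), as did all 11 of groups 5-8 (2.64e-06) and all 6 tested members of groups 9-13 (0.0015). With an estimated correlation each of these lists had an adjusted p = 0.395. HOXB4 (ENSG00000182742, chromosome 17, 48575513 to 48580111, minus strand, GRCh38) was at 129 ± 10.1 CPM in posterior and 1.90 ± 0.93 CPM in anterior organoids, a 68.7-fold difference (log2 6.10, SE 0.32, adjusted p = 5.16e-06). HOXC6 was 80-fold higher at 371 ± 63 CPM, and HOXC9 (ENSG00000180806, chromosome 12, 53994895 to 54003337, plus strand) was 102-fold higher at 135 ± 15.6 CPM. Among genes of at least 5 CPM that met the naming rule, HOXA10 (ENSG00000253293, chromosome 7, 27170591 to 27180261, minus strand) had the largest fold toward posterior organoids with all libraries, 229-fold. Without anterior replicate 3 it was 456-fold, below CNTNAP4 at 544-fold. HOXB9, chosen after its values were seen, was the most abundant HOX gene at 1460, 1196 and 1515 CPM in posterior replicates 1, 2 and 3. Expression ended sharply along the clusters. Paralog group 9 summed to 1780 ± 214 CPM and group 10 to 85.7 ± 20.5 CPM in posterior organoids, while groups 11, 12 and 13 summed to 0.156 ± 0.059, 0.158 ± 0.076 and 0.383 ± 0.127 CPM. The 10 untested members of groups 9-13 were too low for the test. HOXA10 and HOXA9 overlap a readthrough gene, HOXB4 overlaps HOXB3, and HOXC6 overlaps HOXC4 and HOXC9 on the same strand, so the split of reads between these neighbours is uncertain.

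**Figure D1:**
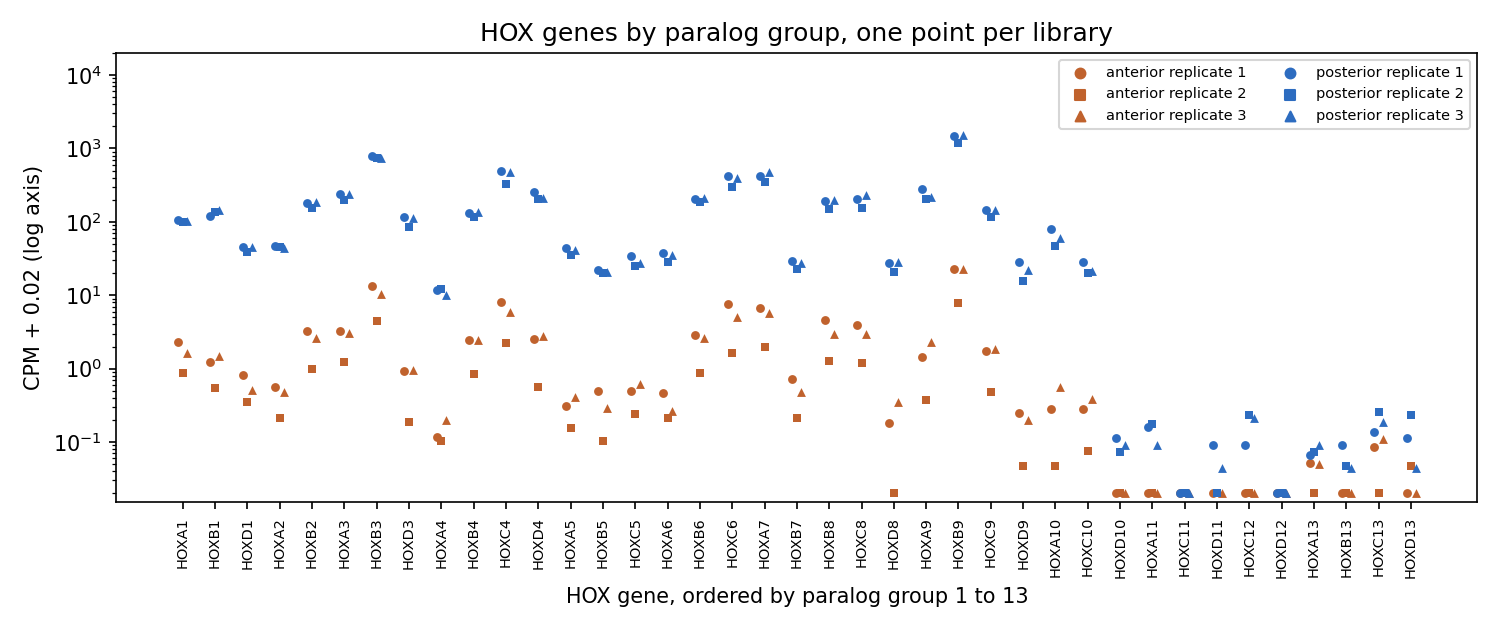
CPM of each HOX gene in each of the 6 libraries on a log axis, with 0.02 added to each value and genes ordered by paralog group. Orange points are anterior and blue points posterior replicates. Posterior points of the tested genes lie above all anterior points, and the genes at the right, from HOXD10 on, are near 0 in every library.

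Caudal genes followed the same direction. Of 13 tested genes of the caudal epiblast and neuromesodermal progenitors, which give rise to spinal cord and trunk mesoderm, 10 rose and 2 fell in posterior organoids (camera adjusted p = 0.00565). CDX2 (ENSG00000165556, chromosome 13, 27962137 to 27971139, minus strand), a caudal homeobox gene, was 33.8-fold higher at 276 ± 75.8 CPM (adjusted p = 0.000111). CDX4 was 101-fold higher at 131 ± 24.2 CPM and SP8 20.6-fold higher at 113 ± 11.8 CPM. TBXT, the Brachyury gene of the primitive streak and notochord, was at 19.8 ± 13.9 CPM in anterior and 17.7 ± 5.33 CPM in posterior organoids and did not pass (log2 -0.16, SE 0.49, adjusted p = 0.796). Its sign turned without anterior replicate 1 (log2 0.59, adjusted p = 0.0781) and without posterior replicate 2 (0.01, adjusted p = 0.993). Over all its alternatives the adjusted p of TBXT ran from 0.0781 to 1. Among 11 tested paraxial mesoderm genes, the precursors of the somites, 10 rose and 0 fell (camera adjusted p = 0.00349). These included HES7 at 13.3 ± 2.25 CPM (12.3-fold), TBX6 at 7.87 ± 2.52 CPM (4.67-fold) and FOXC2 at 10.8 ± 5.93 CPM (44.4-fold). With an estimated correlation the caudal and the paraxial list each had an adjusted p = 0.395. Without posterior replicate 3, 1 rather than 2 caudal genes fell.

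Forebrain genes moved the other way. Of 11 tested forebrain and eye-field transcription factors, 9 were higher in anterior and 2 in posterior organoids (camera adjusted p = 0.00565, and adjusted p = 0.395 with an estimated correlation). OTX2 (ENSG00000165588, chromosome 14, 56799905 to 56810479, minus strand), a head and forebrain regulator, was at 112 ± 38.5 CPM in anterior and 0.468 ± 0.615 CPM in posterior organoids. That was a 235-fold difference (adjusted p = 9.64e-05), and 967-fold without posterior replicate 3. EMX1 was 136-fold higher in anterior organoids at 12.8 ± 0.83 CPM and HESX1 8.5-fold higher at 14.2 ± 1.55 CPM. SIX3 was at 8.78 ± 3.13 CPM in anterior organoids with 0 counts in the posterior libraries, at least 363-fold lower there by the floor of 3 counts over the group. Among 11 tested midbrain, isthmus and rhombomere genes 8 rose and 2 fell in posterior organoids (camera adjusted p = 0.0371). FGF8 was 15.3-fold higher at 3.09 ± 1.16 CPM, while IRX2 was 5.28-fold higher in anterior organoids at 109 ± 17.2 CPM. This call was lost without anterior replicate 2 (adjusted p = 0.0593), and over the alternatives its adjusted p ran from 0.000171 with fry to 0.395 with an estimated correlation.

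General neural progenitor genes were mostly higher in posterior organoids. Of 14 tested, 10 rose and 1 fell (camera adjusted p = 0.00458, and adjusted p = 0.395 with an estimated correlation). NCAM1, a neural cell adhesion molecule, was 17.1-fold higher at 388 ± 40 CPM, DACH1 24.8-fold higher at 57.2 ± 15.7 CPM and PROM1 3.6-fold higher at 165 ± 8.79 CPM. SOX2 (ENSG00000181449, chromosome 3, 181711924 to 181714436, plus strand), shared by stem cells and neural progenitors, was at 329 ± 34.8 CPM in anterior and 412 ± 42.7 CPM in posterior organoids (1.25-fold, adjusted p = 0.0224). Its call was lost without anterior replicate 1 (adjusted p = 0.0742), posterior replicate 2 (0.0718) or posterior replicate 3 (0.0569), and in the test beyond 1.5-fold (1), with a range over its alternatives from 0.00319 to 1. SOX1 was at 0.169 ± 0.063 CPM in anterior and 22.8 ± 16.5 CPM in posterior organoids (132-fold, and 77.5-fold without posterior replicate 2). PAX6 (ENSG00000007372, chromosome 11, 31784779 to 31818062, minus strand), a regulator of eye and neural tube, was at 1.17 ± 0.20 and 32.8 ± 32.7 CPM (27.7-fold, adjusted p = 0.00313). It was at 70.4 CPM in posterior replicate 2 against 12.2 and 15.7 CPM in posterior replicates 1 and 3, and its fold without posterior replicate 2 was 11.8. PAX6 overlaps another gene in the annotation, which leaves part of its reads uncertain.

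Genes of the dorsal neural tube were higher in posterior organoids, where 12 of 13 tested rose and 1 fell (camera adjusted p = 0.00206, and adjusted p = 0.395 with an estimated correlation). PAX3, a dorsal neural and somite regulator, was 71.8-fold higher at 79.8 ± 24.9 CPM and PAX7 14.3-fold higher at 3.16 ± 1.10 CPM, while LMX1B was 6.65-fold higher in anterior organoids. Of 6 tested intermediate neural tube transcription factors, 5 rose and 1 fell (camera adjusted p = 0.0421). PRDM12 was 97.3-fold and IRX3 33.1-fold higher, and GSX1 was 38.7-fold higher in anterior organoids at 1.40 ± 0.27 CPM, or 87-fold without posterior replicate 1. The call of this list was lost with the replicate number as a block (adjusted p = 0.0515) and without anterior replicate 1 (0.0547), 2 (0.0618) or 3 (0.056), and its adjusted p ran from 0.000403 with fry to 0.395 with an estimated correlation. Among 10 tested Hedgehog and ventral genes, 0 rose and 5 fell (camera adjusted p = 0.0423), or 1 rose and 4 fell without anterior replicate 1. FOXA2 (ENSG00000125798, chromosome 20, 22581005 to 22585455, minus strand), a regulator of notochord, floor plate and endoderm, was at 153 ± 46.2 CPM in anterior and 0.194 ± 0.117 CPM in posterior organoids (762-fold, adjusted p = 1.82e-06). SHH was at 18.3 ± 8.68 CPM in anterior organoids with 6 counts over the posterior libraries, and GLI1 was 9.55-fold higher in anterior organoids. The call of the ventral list was lost without anterior replicate 1 (adjusted p = 0.0644) or 2 (0.0786), with a range from 0.00202 with fry to 0.395 with an estimated correlation.

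Pluripotency genes were higher in anterior organoids, where 11 of 12 tested were higher and 1 was lower (camera adjusted p = 0.00151, and adjusted p = 0.395 with an estimated correlation). The number lower was 0 without posterior replicate 3 and 0 without anterior replicate 1. POU5F1 (ENSG00000204531, chromosome 6, 31164337 to 31180731, minus strand), which encodes OCT4, was at 1060 ± 207 CPM in anterior and 14.8 ± 20 CPM in posterior organoids (log2 -6.17, SE 1.27, adjusted p = 0.0105). Its 71.8-fold difference was 329-fold without posterior replicate 3, which held 37.9 CPM against 3.61 and 2.82 CPM in posterior replicates 1 and 2. L1TD1 was 10.1-fold higher at 1020 ± 131 CPM, DNMT3B 4.02-fold higher at 1080 ± 177 CPM and DPPA4 3.82-fold higher at 534 ± 12.6 CPM in anterior organoids. POU5F1 has near-identical pseudogenes and overlaps another gene, so its reads may be shared. Markers of other cell types moved with the groups as well. Of 9 tested surface ectoderm and placode genes, 6 were higher in anterior organoids and 1 in posterior (camera adjusted p = 0.0299), among them EPCAM (23.2-fold, 282 ± 65.3 CPM) and KRT19 (7.7-fold, 118 ± 3.96 CPM), both general epithelial genes. Of 6 tested endoderm genes 4 were higher in anterior organoids and 0 in posterior (camera adjusted p = 0.00902), with FOXA2 again among them. AFP was at 1.89 ± 0.42 CPM with 1 count in the posterior libraries, a ratio of 228 with a 95% counting interval from 40.3 to 9030. This was 149 without posterior replicate 1 and at least 49.9 without posterior replicate 3, which held that count. With an estimated correlation the surface ectoderm and the endoderm list each had an adjusted p = 0.395. Of 10 tested neural crest genes 7 were higher in anterior and 2 in posterior organoids, without passing as a list (camera adjusted p = 0.0811). FOXD3, shared by neural crest and stem cells, was 134-fold higher in anterior and SNAI2 10.7-fold higher in posterior organoids. Of 8 tested lateral mesoderm and endothelial genes 6 were higher in anterior and 1, PDGFRA (20.6-fold), in posterior organoids (camera adjusted p = 0.149). Of 10 tested neuron genes 6 were higher in posterior and 4 in anterior organoids (camera adjusted p = 0.559), with DCX 4.1-fold higher in anterior organoids. NEUROG2 had 3 counts in the anterior libraries against 5.04 ± 1.89 CPM in posterior, a ratio of 167 with a 95% counting interval from 56.7 to 810, and 336 without anterior replicate 3, on 1 count.

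**Figure D2:**
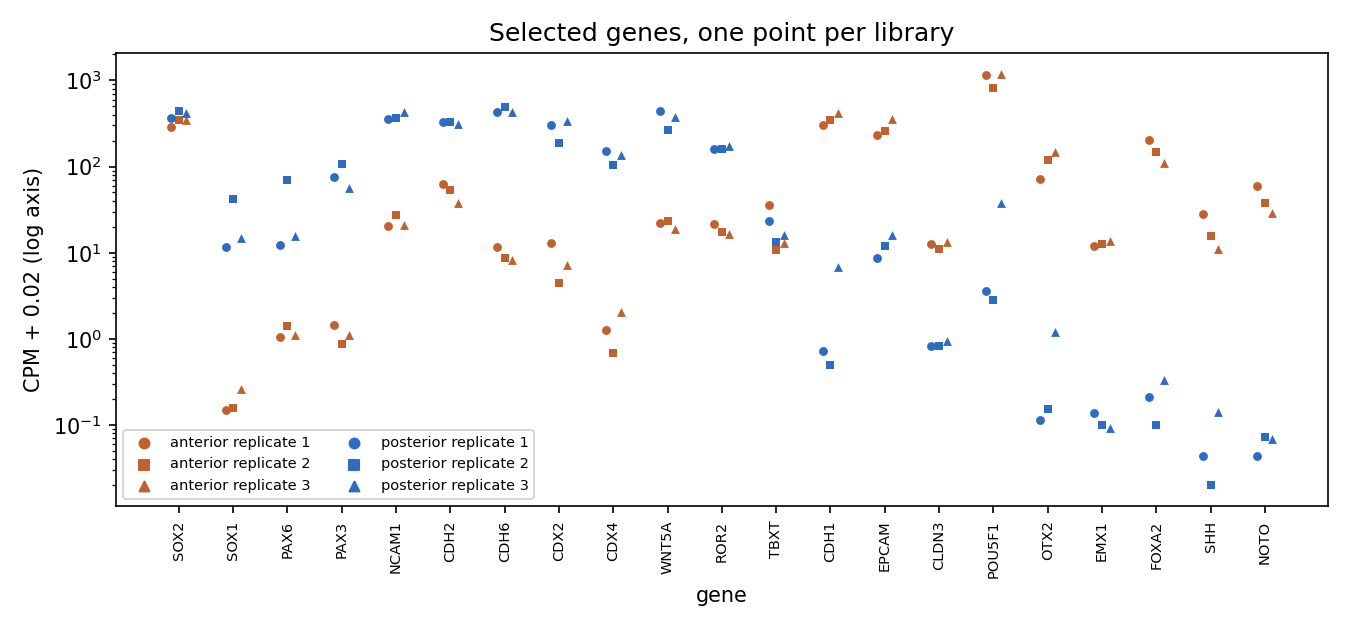
CPM of 21 genes in each of the 6 libraries on a log axis, with 0.02 added to each value. Orange points are anterior and blue points posterior replicates. SOX2 and TBXT lie at similar levels in both groups, and POU5F1, CDH1 and OTX2 lie higher in posterior replicate 3 than in the other posterior libraries.

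With all libraries, the naming rule gave the 10 largest fitted folds toward anterior organoids among genes of at least 5 CPM. Besides SIX3, SHH and FOXA2, these were TFF3, DCN, NOTO, FOXB2, SHISA2, WDR49 and RARRES2. The ranks of SIX3 and DCN are uncertain, as 0 posterior counts give only a lower bound of the fold. NOTO (ENSG00000214513, chromosome 2, 73202258 to 73212513, plus strand), a homeobox gene of the node and notochord, was at 42.1 ± 16.0 CPM with 5 counts over the posterior libraries (adjusted p = 2.23e-06). TFF3, a secreted mucosal peptide, was at 44.7 ± 7.15 CPM with 2 posterior counts, a ratio of 2720 with a counting interval from 752 to 22400, and 1790 without posterior replicate 3. WDR49 was at 6.66 ± 2.68 CPM with 2 posterior counts, a ratio of 407 with an interval from 112 to 3360, and 266 without posterior replicate 1. DCN, the proteoglycan decorin, was at 5.20 ± 2.83 CPM with 0 posterior counts, at least 215-fold lower there. SHISA2 was 353-fold and RARRES2 297-fold higher in anterior organoids. Toward posterior organoids, besides HOX genes, CNTNAP4 reached 114 ± 18.1 CPM (200-fold, and 544-fold without anterior replicate 3), ASXL3 191 ± 15.8 CPM (165-fold) and MMRN1 9.54 ± 5.29 CPM (151-fold). RIPPLY1, a somite gene, was at 32.1 ± 21.9 CPM (151-fold, and 415-fold without anterior replicate 3), and it overlaps CLDN2.

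Cadherins differed by type. CDH1 (ENSG00000039068, chromosome 16, 68737225 to 68835548, plus strand), which encodes E-cadherin, was at 358 ± 61.1 CPM in anterior and 2.64 ± 3.54 CPM in posterior organoids (134-fold, adjusted p = 0.00225, and 593-fold without posterior replicate 3). CDH2 (ENSG00000170558, chromosome 18, 27950966 to 28177446, minus strand), which encodes N-cadherin, was at 51.1 ± 12.5 and 324 ± 14 CPM (6.34-fold higher in posterior, adjusted p = 3.87e-06). CDH6 was 47.1-fold higher in posterior organoids at 449 ± 34.4 CPM, and CDH3, P-cadherin, 13.8-fold higher in anterior organoids at 135 ± 26.1 CPM. Over the list of 20 cadherins and protocadherins, 10 rose and 6 fell (camera adjusted p = 0.305). Of 25 apicobasal polarity and tight junction genes, 15 were higher in anterior and 7 in posterior organoids (camera adjusted p = 0.0254, and adjusted p = 0.395 with an estimated correlation). CLDN3 was 14.3-fold, LLGL2 6.28-fold, F11R 3.52-fold and PATJ 3.32-fold higher in anterior organoids. TJP1 (ENSG00000104067, chromosome 15, 29699367 to 29968865, minus strand), which encodes ZO-1, was at 181 ± 9.48 CPM in anterior and 150 ± 3.21 CPM in posterior organoids (1.21-fold, adjusted p = 0.00983), and did not pass the test beyond 1.5-fold (adjusted p = 1, the highest over its alternatives).

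Of 20 planar cell polarity and intercalation genes, which direct cell rearrangement in the plane of an epithelium, 13 rose and 3 fell in posterior organoids (camera adjusted p = 0.0197, and adjusted p = 0.395 with an estimated correlation). WNT5A (ENSG00000114251, chromosome 3, 55465715 to 55490539, minus strand), a ligand of this pathway, was 16.8-fold higher at 360 ± 88.7 CPM and its receptor ROR2 8.97-fold higher at 166 ± 6.53 CPM. FZD6 was 2.79-fold higher, and ROR1 was 5.66-fold higher in anterior organoids at 113 ± 21.8 CPM. Of 24 basement membrane and integrin genes, 15 rose and 4 fell (camera adjusted p = 0.0371). NID1 was 4.67-fold higher at 359 ± 32.2 CPM and COL4A2 3.18-fold higher at 495 ± 42.1 CPM, while the integrin gene ITGA6 was 5.43-fold higher in anterior organoids at 365 ± 63.7 CPM. This call was lost without anterior replicate 3 (adjusted p = 0.0628), and its adjusted p ran from 0.00366 with fry to 0.395 with an estimated correlation. Of 20 actomyosin genes, 4 rose and 9 fell (camera adjusted p = 0.292), with MYH14 5.32-fold higher in anterior and ACTA2 5.01-fold higher in posterior organoids. Of 13 YAP and TAZ target genes, 7 rose and 2 fell (camera adjusted p = 0.0634), among them AJUBA (4.6-fold) and AMOTL2 (4.53-fold). This list passed without posterior replicate 1 (adjusted p = 0.0479) or 3 (0.0499), with a range from 0.00108 with fry to 0.395 with an estimated correlation. YAP1 itself was at 232 ± 26.5 CPM in anterior and 532 ± 21.8 CPM in posterior organoids (2.29-fold, adjusted p = 4.56e-06).

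Target genes of the pathways that were manipulated moved in both directions. RNA was taken at day 6, whereas the anterior inhibition ended at day 3, and both groups received BMP inhibition. Of all tested genes 62.2% were called, and 49.1% of the called genes were higher in posterior organoids. The counts below therefore do not by themselves read out the pathways under treatment. Of 13 WNT response genes, 7 rose and 2 fell (camera adjusted p = 0.092), with LEF1 18.4-fold higher at 122 ± 24.3 CPM. Without posterior replicate 3, the fall was seen in 1 gene and the list passed (adjusted p = 0.0383, range over the alternatives 0.0142 with fry to 0.604 with an estimated correlation). Of 12 retinoic acid response genes, 6 rose and 4 fell (camera adjusted p = 0.354). CRABP2, a retinoic acid binding protein, was 7.34-fold higher at 442 ± 22.7 CPM, whereas the retinaldehyde reductase gene DHRS3 was 19.5-fold higher in anterior organoids. Of 13 FGF and ERK response genes, 7 rose and 4 fell (camera adjusted p = 0.25), with DUSP6 1.87-fold and DUSP4 3.76-fold higher. Of 10 tested BMP response genes, 5 rose and 3 fell (camera adjusted p = 0.245), with SMAD6 6.61-fold and ID2 5.55-fold higher. Of 9 NODAL and TGF-beta response genes, 4 rose and 4 fell (camera adjusted p = 0.901), with PMEPA1 7.1-fold higher in anterior and LEFTY2 8.88-fold higher in posterior organoids.

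**Figure D3:**
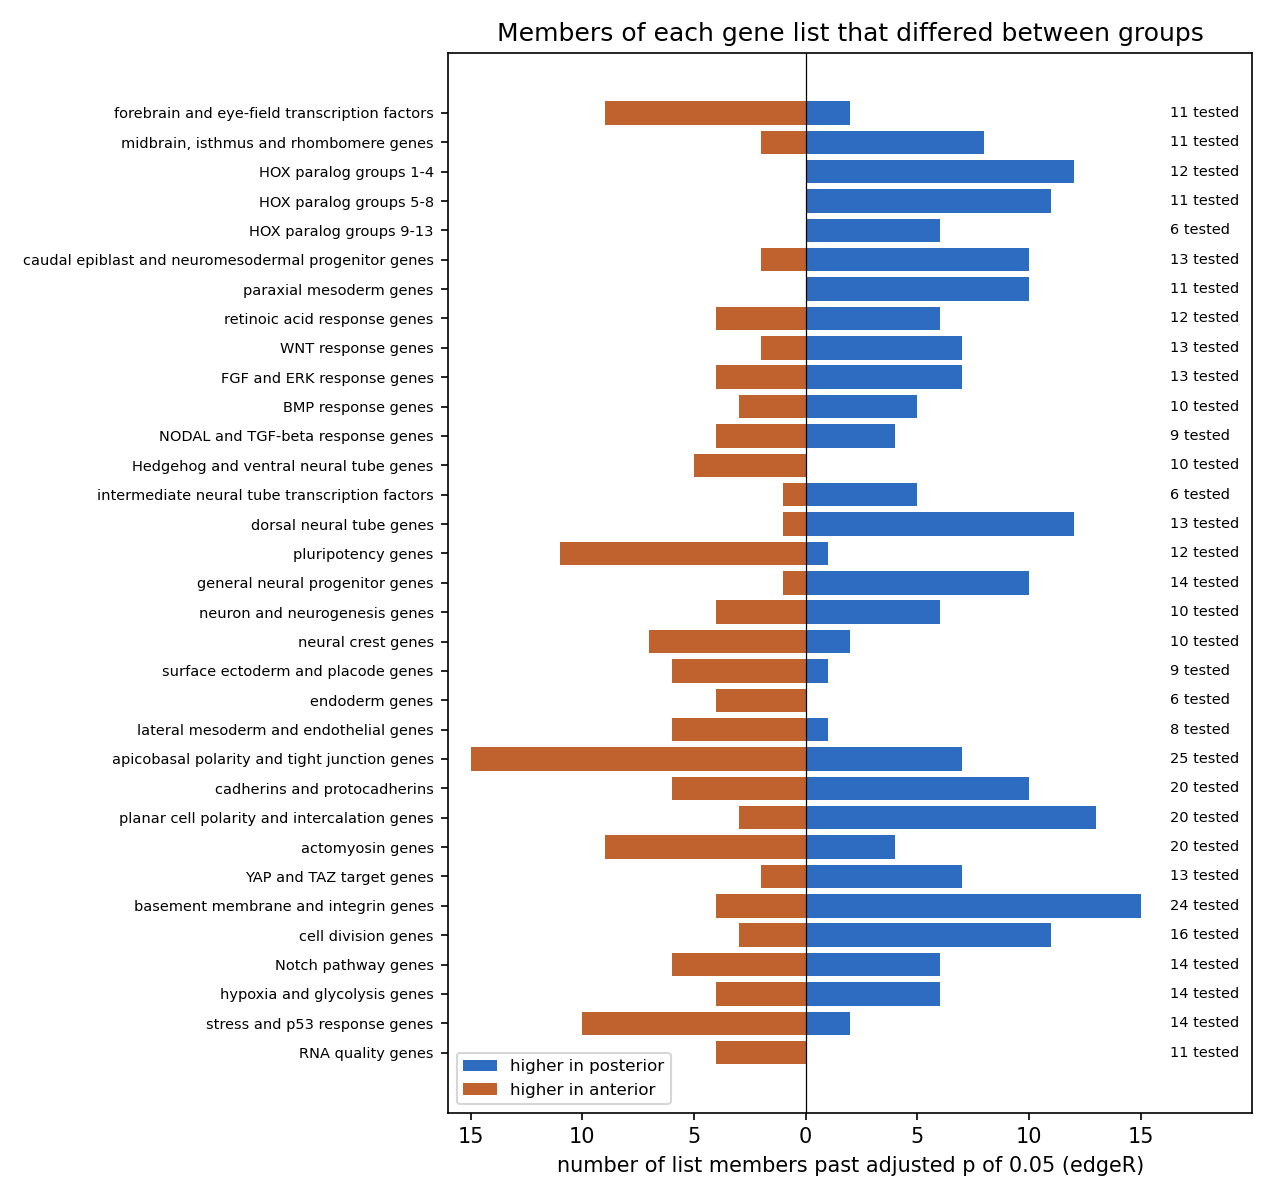
Number of members of each of the 33 gene lists that passed the edgeR test, with genes higher in posterior organoids as blue bars to the right and genes higher in anterior organoids as orange bars to the left. The number of tested members stands at the right, and the HOX and paraxial mesoderm lists have blue bars alone.

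Of 16 cell division genes, 11 rose and 3 fell (camera adjusted p = 0.0575). MKI67 was 1.68-fold and CENPF 2.22-fold higher in posterior organoids, and BUB1 1.99-fold higher in anterior organoids. MKI67 did not pass the test beyond 1.5-fold (adjusted p = 0.0525, the highest over its alternatives). The number that rose was 7 without posterior replicate 3 and also 7 without anterior replicate 1. The list passed with the replicate number as a block (adjusted p = 0.0478), with total counts alone (0.0486), and without anterior replicate 3 (0.0304) or posterior replicate 1 (0.0433), within a range from 0.00871 with fry to 0.558 with an estimated correlation. Of 14 tested Notch pathway genes, 6 rose and 6 fell (camera adjusted p = 0.706), with DLL3 5.5-fold higher in posterior and LFNG 6.21-fold higher in anterior organoids. The median log2 fold change of the Notch list was -0.10, while its mean was 0.20 and its test pointed up. Of 14 hypoxia and glycolysis genes, 6 rose and 4 fell (camera adjusted p = 0.435), with the median at 0.19, the mean at -0.09 and the test pointing up. ADM, adrenomedullin, was 147-fold higher in anterior organoids at 91 ± 7.38 CPM, and PDK1 3.56-fold higher in posterior organoids. Of 14 stress and p53 response genes, 10 were higher in anterior and 2 in posterior organoids (camera adjusted p = 0.0132, and adjusted p = 0.395 with an estimated correlation). ASNS, asparagine synthetase, was 5.39-fold higher at 170 ± 19.5 CPM, CHAC1 9.41-fold and DDIT3 2.47-fold higher in anterior organoids. Of 11 tested RNA quality genes, 4 were higher in anterior and 0 in posterior organoids (camera adjusted p = 0.0839), with MT-CO2 1.38-fold higher, which did not pass the test beyond 1.5-fold (adjusted p = 1, the highest over its alternatives). This list passed without posterior replicate 2 (adjusted p = 0.0381, range 0.0375 with fry to 0.564 with an estimated correlation).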

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

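The counts of members without posterior replicate 3 and without anterior replicate 1 were chosen after the data were seen. The number of genes higher in posterior and in anterior organoids stayed within 1.5 times of 4879 and 5055 in every alternative except the test beyond 1.5-fold, which gave 1968 and 2352 because it asks for a larger change. Leaving out 1 library at a time gave 4233 to 4789 genes higher in posterior and 4381 to 4965 higher in anterior organoids, with between 85.3% and 92.2% of the 9934 calls kept. With the replicate number as a block, 5198 and 5284 genes were called and 99.3% of the calls were kept. Of the gene lists, the block changed the calls of the intermediate neural tube and the cell division list, both given with those lists, and no other call of a list or named gene. With upper-quartile factors 45.4% of the called genes were higher in posterior organoids, against 49.1% with TMM.

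Of the 33 lists, 18 passed with the preset correlation, 0 with an estimated correlation (lowest adjusted p = 0.395) and 29 with fry, which asks a different question. Leaving out 1 library gave 15 to 20, the block 18 and total counts alone 19. The NODAL and TGF-beta list turned direction with fry (adjusted p = 0.931) and without posterior replicate 3 (0.869), and the lateral mesoderm list with fry (0.887), none of them past the threshold. Leaving out 1 library gave that NODAL list adjusted p-values from 0.758 to 0.993. The log2 fold change of TBXT turned to 0.046 with limma-voom, 0.588 without anterior replicate 1 and 0.008 without posterior replicate 2, with -0.462 to 0.588 over the libraries left out. The cause was not tested. Among single named genes 23 results under an alternative lost their call, among them results for SOX2, TJP1, SPRED2, TUBB3, TYMS, MKI67 and 3 mitochondrial genes, and 2596 kept direction and side of the threshold. Depth limits genes near the floor, such as HOX groups 11 to 13, which could not be tested. Ratios from counts, for genes with at most 3 counts in a group, were recomputed without each library in turn, which was chosen after the counts were seen. Those that moved by over 1.5 times are given with the genes, except the bounds of SIX3, DCN and TEKT1, which fell to at least 237, 141 and 115 without posterior replicate 1 and at least 239, 142 and 116 without posterior replicate 3, since fewer libraries carry the floor of 3 counts.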

Other observations

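All tests of explanations in this part were chosen after the result was seen, except the split of the libraries. A further gene group that set anterior organoids apart was that of motile cilia. A list of 24 motile cilia genes was written after 6 members had been seen or may have been seen. Of the other 18, 13 were higher in anterior and 3 in posterior organoids, and 2 did not pass (camera p = 0.00462, p = 0.391 with an estimated correlation). The 3 higher in posterior organoids were DNAH11 (49.4 against 25.9 CPM), RFX3 (78.8 against 55.1 CPM) and CCDC39 (21.2 against 15.9 CPM). RFX2 and CFAP53 did not pass. FOXJ1, the master regulator of motile cilia, was at 134 ± 63.6 CPM in anterior and 6.96 ± 2.72 CPM in posterior organoids (19.2-fold, edgeR adjusted p = 0.000258), and DNAH5, a dynein heavy chain, at 80.9 ± 23 and 0.771 ± 0.215 CPM (105-fold). TEKT1 was at 4.42 ± 2.55 CPM with 0 posterior counts, at least 176-fold lower there. Libraries of a group also differed among themselves. In anterior replicates 1, 2 and 3, CHRD was at 1150, 696 and 344 CPM, FOXJ1 at 206, 107 and 87.7 CPM and NOTO at 59.7, 38 and 28.7 CPM. SOX1 was at 41.8 CPM in posterior replicate 2 against 11.7 and 14.9 CPM in replicates 1 and 3, IRX3 at 64.2 against 23.2 and 32.4 CPM, and the somite gene MEOX1 at 4.61 CPM in replicate 3 against 21.9 and 30.6 CPM in replicates 1 and 2.

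The real grouping called 9934 genes and the highest of the other splits of the 6 libraries called 0, so 1 of 10 splits gave as many. The 3 other splits that part all 3 same-numbered pairs also called 0. With 10 splits no share under 0.05 can be reached, so these splits are too few for a test at that level. Each other split also mixes anterior and posterior libraries on both sides, which widens the spread within a side. A count of 0 there was thus likely in advance and adds no support.

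NOTO, FOXA2 and SHH were abundant in anterior organoids, together with CHRD at 732 ± 406 CPM (123-fold). Definitive endoderm as the main source is argued against by SOX17, GATA4 and GATA6, which stayed at or below 0.212 CPM in each anterior library. CXCR4 was 2.55-fold higher in posterior organoids, but HHEX was higher in anterior organoids (0.693 against 0.0495 CPM, adjusted p = 5e-05). HHEX is 1 of the 4 genes of the endoderm list that were higher there, and FOXA2, which belongs to the pattern, is another. The remaining genes were AFP at 1.89 CPM and APOA1 at 1.87 CPM, both low, so a few such cells stay open. Floor plate cells, which express FOXA2 and SHH, stay open. Node- or notochord-like cells with motile cilia are a candidate source, since 13 of the 18 motile cilia genes not seen before were higher in anterior organoids. Other ciliated cells would show this too, and DNAH11, RFX3 and CCDC39 were higher in posterior organoids. Against a full notochord profile, NOG was 7.85-fold higher in posterior organoids. TBXT, at 35.8, 10.7 and 12.9 CPM in anterior replicates 1, 2 and 3, did not pass the test (log2 0.588 without anterior replicate 1, -0.462 without anterior replicate 2). As TBXT is also a gene of the caudal list and was at 17.7 CPM in posterior organoids, this comparison cannot decide. Node- or notochord-like cells remain a hypothesis.

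Anterior libraries held low HOX counts at 1.61%, 0.495% and 1.41% of the posterior level in replicates 1, 2 and 3, over 29 genes. Reads or RNA carried over from posterior organoids would add the same share to other genes restricted to posterior organoids. In anterior replicate 1 the lowest such share over 12 sets of genes was 0.461% (99.6% counting interval 0.304 to 0.667), below what the HOX level needs. In replicates 2 and 3 it was 0.559% (0.411 to 0.741) and 1.21% (0.973 to 1.47), against HOX shares of 0.495% and 1.41%, which does not exclude carry-over. Each set gives only an upper limit, since anterior organoids may express its genes themselves. Shares of up to 4.59% and 4.82% in other sets therefore do not count against carry-over. An upper limit cannot show that carry-over took place either, so it cannot be told. Shares of single HOX genes ran from 0% to 0.829% in replicate 2 and from 0.712% to 2.1% in replicate 3, and whether this spread exceeds that between libraries was not decided. The reading depends on the gene set: with the set used first, 10 genes of at least 50 CPM, the shares were 1.27%, 1.34% and 1.5%, with which replicate 1 was undecided and the reading of replicate 2 depended on the form of the rule, and a few caudal cells or weak transcription in many cells stay open, and no biological explanation was tested.

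Posterior replicate 3 held POU5F1 at 3.56% of the anterior mean, TDGF1 at 12 CPM against 0.427 and 0.527 CPM, and NANOG at 2.36 against 0.237 and 0.0791 CPM. Without this library the folds of POU5F1, TDGF1 and NANOG were 329, 728 and 153. Carry-over from anterior organoids is argued against, since the lowest share of other genes restricted to anterior organoids was 0.232% (0.126 to 0.388, on 28 counts) and 1.67% with the set used first here, 20 genes of at least 50 CPM, although larger sets of more abundant genes, which posterior organoids also express, reached 3.55% to 7.15%. Whether undifferentiated stem cells were present cannot be told. Without the 3 genes noticed first and FGF4, 8 of 8 pluripotency genes were highest there among the posterior libraries. Their excess over the other posterior libraries ran from 0.477% to 32.5% of the anterior mean. These percentages refer to anterior organoids, and no stem cell library was measured. Their spread therefore cannot decide whether a single share of such cells was present. TDGF1, NANOG and POU5F1 have pseudogenes that can share reads, and slower differentiation of all cells stays open.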
